A study of Mus musculus with 6 samples.

How the data were processed

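White adipose tissue of mice on a high-fat diet (HFD) was profiled by RNA sequencing in 6 samples. The 3 HFD samples received the diet alone, and the 3 THBru samples also received tetrahydroberberrubine (THBru), a small molecule, at 50 mg/kg/day. The labels do not name the fat depot, the sex of the mice or whether the samples came from separate animals, so each p-value measures only the spread between these samples. Per the labels' protocols, total RNA was extracted with Trizol, poly(A) RNA was fragmented, the second cDNA strand was marked with dUTP and removed, and dual-indexed libraries were sequenced as paired reads on an Illumina NovaSeq instrument.

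The deposited table holds whole-number counts per gene, named as counts per the file headers and not normalized. It also holds FPKM values (fragments per kilobase of transcript per 1e6 fragments) for the same genes and samples, as calculated by the authors. For at least 99.99% of genes compared, the ratio of count to FPKM between any 2 samples lay within 0.05 log2 of its median, among genes with at least 200 counts. Cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, DESeq2 and edgeR are named in the submitters' processing notes without their roles, and the program that produced the counts, the strand setting and the genome build are not given in the sources used here. Of the gene identifiers, 99.7% are in GENCODE M21, and 91.0% of those have the coordinates of that annotation on GRCm38, so coordinates are given as in the table and read as GRCm38. Rows sharing a symbol were summed, which turned 32819 rows into 32759 genes.

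The test planned for FPKM values was limma. Because the table also held counts, the contingency written in the same plan was used: edgeR 4.0.16 quasi-likelihood tests with robust empirical Bayes and TMM scaling, THBru against HFD without further covariates, on the 16140 genes with a mean FPKM of at least 0.5. The total count of each sample served as its library size. All tests were two-sided. Fold changes are log2 values with their standard errors, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Group means with SD in the text and list medians in log2 CPM use TMM-scaled counts per 1e6 counts (CPM). Levels in single libraries and summed levels of lists are CPM of the total count unless TMM scaling is named. For 9 genes of thermogenesis and adipocyte signalling, group means of log2(FPKM + 0.5) were compared by exact permutation tests over the 20 relabellings of the samples. Their smallest possible p is 0.1. A fold change on that scale understates the change of low genes.

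Gene lists were tested with camera (limma 3.58.1, R 4.3.3) at a preset correlation of 0.01, on 47 lists of adipocyte, mitochondrial, stromal, immune, carry-over tissue and stress genes, each with at least 5 tested genes. The GO and KEGG terms that the deposited table pairs with its genes were tested the same way where 10 to 300 genes were tested, 2283 terms in all. Camera with an estimated correlation and fry were run beside it. The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. After the data were seen, 5 lists were added (seminal vesicle, kidney, ciliated epithelium, sperm and spermatid, general epithelium), for levels per library only and without a test.

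Named genes followed 5 parts of a rule. Part 1 always names Ucp1, Ppargc1a, Ppargc1b, Cidea, Dio2, Prdm16, Cox8b, Elovl3, Lep and Adipoq. Part 2 takes the 10 largest rises and the 10 largest falls among genes past the threshold with no overlap between the groups and a mean FPKM of at least 2 in the higher group, without predicted genes, pseudogenes and receptor segments. Places left in a direction were filled by the smallest unadjusted p under the same other conditions, so again without overlap between the groups. Part 3 takes up to 4 members with the smallest p from each list past its test and from the thermogenic, respiratory complex, fatty acid oxidation, lipogenesis, macrophage and matrix lists, of which the first 2 are given. Part 4 takes up to 3 members of each named term, and part 5 the 2 most abundant members of each carry-over list. Some genes that the rule selects are not reported here. Other genes named were chosen after their values were seen: the 2 genes shared by the most raised genes of the 3 THBru libraries, and Gpx5, the most abundant gene of THBru 3.

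Total counts ranged from 67.2e6 to 77e6 per sample, so 3 counts, the upper limit that a count of 0 allows, correspond to 0.0390 to 0.0446 CPM in a single library. Shares of counts in a single library carry 95% Wilson intervals. These intervals and limits cover counting error only. No 2 libraries agreed within sampling noise, with a chi-square per gene of at least 228 for each pair.

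The steps were tested on simulated counts for the 16140 genes of THBru against HFD, with 200 genes changed. With the spread of all 6 libraries, none of 69 genes changed 2-fold, 1.52% of 66 changed 4-fold and 46.2% of 65 changed 8-fold were recovered, with 4 false calls. With the spread of the HFD libraries alone, 19.0%, 75.8% and 90.1% were recovered at 2-fold, 4-fold and 8-fold, with 11 false calls. A list of 25 genes shifted by 1 log2 unit was called in both simulations, and 0 of 40 unshifted lists were called. The simulated genes were drawn independently, so these lists could not show how the list test behaves when genes vary together. All simulated libraries were drawn from the mean HFD levels, so none held the transcripts of other organs described below. Recovery and false calls may therefore differ in the real THBru libraries.

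Alternatives were DESeq2 1.42.0, limma on FPKM with other pseudocounts, scalings and weights, other filters, a replicate block and each sample left out. Alternatives chosen after seeing the data were THBru sample 2 alone, scaling to the mature adipocyte list, both together, scaling to total counts, and DESeq2 size factors in edgeR. Permutation tests used SciPy 1.17.1 and plots matplotlib 3.10.9.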

Results

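The question was which biological processes THBru, tested as an anti-obesity compound, alters in white fat of mice on a high-fat diet, with thermogenesis through PGC1α (encoded by Ppargc1a) as the process the study names. RNA was measured in 3 HFD and 3 THBru samples. Total counts were 77e6, 69.3e6 and 74.0e6 in HFD 1 to 3 and 72.1e6, 68.3e6 and 67.2e6 in THBru 1 to 3.

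Each THBru library held transcripts of an organ other than fat. In THBru 1, the seminal vesicle list took 45.3% of counts (95% Wilson interval 45.31 to 45.33), with Svs2 and Svs5, which encode seminal vesicle secretory proteins, at 17.2% and 7.87%. In THBru 3, the epididymal epithelium list took 3.14% (3.13 to 3.14), with Adam7 at 1.28%, Lcn5 at 0.339% and, outside the list, Gpx5 at 2.44%. In THBru 2, the kidney list took 0.0911% (0.0904 to 0.0918), led by the renal transporters Slc34a1 (360 CPM) and Slc12a3 (139 CPM). Against the HFD mean these summed levels were 740-fold, 808-fold and 616-fold higher, and 11 of 11, 15 of 15 and 11 of 11 list members were raised over 8-fold in the library concerned. The shares differed more: all genes raised over 8-fold and above 5 CPM took 51.1% of counts in THBru 1, 1.97% in THBru 2 and 24.4% in THBru 3. In the other 5 libraries the same lists stayed at 0.0566 to 0.123%, 0.00368 to 0.0115% and 1.2e-04 to 9.7e-04%. The seminal vesicle and kidney lists were written after their genes had been seen, so their counts of 11 of 11 were not a test.

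The mature adipocyte list was lower in THBru 1 and THBru 3 and within the HFD range in THBru 2. It took 2.42, 3.53 and 4.05% of counts in HFD 1 to 3, 0.610% in THBru 1, 2.98% in THBru 2 and 0.323% in THBru 3. Macrophage genes took 0.858, 0.436 and 0.390% in the HFD libraries and 0.0807, 0.247 and 0.0515% in the THBru libraries. The general epithelium list, with Epcam, Cdh1 and keratin genes, was 40-, 17.1- and 72.0-fold above the HFD mean in THBru 1 to 3, ciliated epithelium genes 0.305-, 137- and 33.7-fold, and sperm and spermatid genes 93.0-fold in THBru 3. The ribosomal RNA gene CT010467 took 1.63% of counts in THBru 3 and 0.0795 to 0.159% in the other libraries. Skeletal muscle genes stood at 0.871- to 1.06-fold. Correlations of log2 CPM (Pearson, across genes) were 0.969 to 0.979 among the HFD libraries and 0.792 to 0.848 among the THBru libraries.

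**Figure D1:**
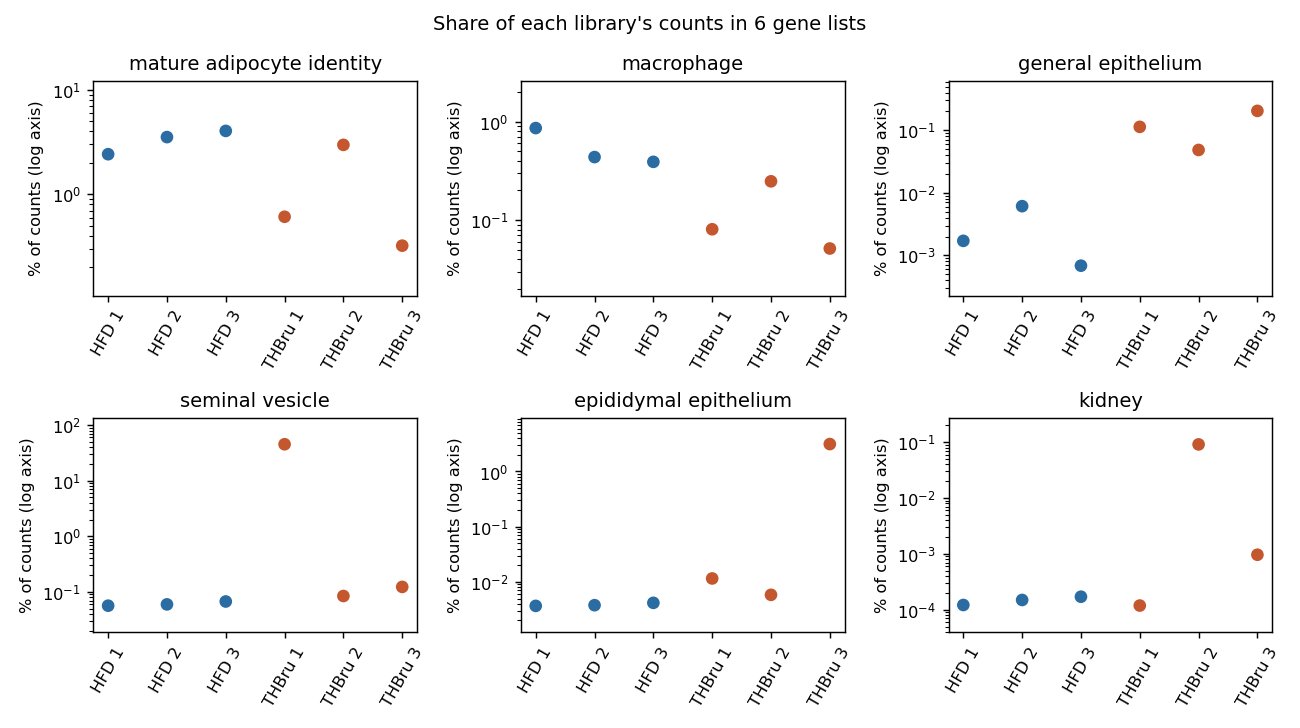
Share of each library's counts (%, log axis) taken by 6 gene lists, 1 point per library, HFD in blue and THBru in orange. Seminal vesicle genes stand at 45.3% in THBru 1, epididymal genes at 3.14% in THBru 3 and kidney genes at 0.0911% in THBru 2, while the adipocyte list is lowest in THBru 1 and THBru 3.

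The first comparison asked which single genes differed between THBru and HFD. Of the 19 genes that rose, 1, Epcam, belongs to a fixed epithelial list. Epcam, an epithelial adhesion molecule, stood at 0.434 ± 0.150 CPM in HFD and 119 ± 85.0 CPM in THBru (SD, n = 3 each; log2 fold change 8.10, SE 0.77; edgeR adjusted p = 0.0486). Ttll10 (7.49), Rnf43 (7.38), Inava (7.20), the serine protease gene Tmprss2 (7.13), B4galnt2 (6.76), Pdzk1ip1 (6.68), the meiotic cohesin gene Rec8 (6.36) and the BMP receptor gene Bmpr1b (6.13) followed, with log2 fold changes in parentheses. Their higher values in 3 of 3 THBru libraries were a condition of the rule. These genes moved beside the epithelial, seminal vesicle, epididymal and kidney transcripts given above.

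No gene was called lower by the edgeR test. The genes with the smallest p among lower genes without overlap between the groups did not pass. They included Fam20c, which encodes a secretory pathway kinase (log2 fold change −2.59, SE 0.39; edgeR adjusted p = 0.103), Arhgap22 (−1.97), Smpd3, a neutral sphingomyelinase gene (−3.05), Anxa1 (−2.27), Tubb2a (−1.52), Gfpt2 (−2.31), Gpr35 (−2.25), Pkp2 (−1.11) and Tuba1a (−1.81). Anxa1 stood at 649 ± 132 CPM in HFD and 134 ± 52.8 CPM in THBru. That the 3 THBru values lay below the 3 HFD values in each of these genes was a condition of their selection. Tubb2a and Tuba1a belong to a family of near-identical tubulin genes, so their counts are uncertain.

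Of 16140 genes, 19 passed at an edgeR adjusted p under 0.05, 19 higher and 0 lower in THBru. At an unadjusted p under 0.05 there were 2248 higher and 1442 lower genes, and DESeq2 called 1670 higher and 1103 lower. Groups did not overlap for 31.8% of genes, where chance gives 10% for a single gene. Genes that vary together between libraries can move this share far from 10% in a single grouping, and the difference was not tested. The count changed with single libraries: 0 genes passed without HFD 1, HFD 2 or HFD 3, 79 without THBru 1, and 817 higher and 735 lower without THBru 2. Without THBru 3, 23 passed, 17 of them among the 19. The lower genes named above were among those called without THBru 2, except Pkp2.

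Epcam (ENSMUSG00000045394) lies on chromosome 17 at 87635979 to 87651106 on the plus strand. Ppargc1a (ENSMUSG00000029167) lies on chromosome 5 at 51454250 to 51567704, minus strand, Ucp1 (ENSMUSG00000031710) on chromosome 8 at 83290352 to 83298452, plus strand, and Lep (ENSMUSG00000059201) on chromosome 6 at 29060220 to 29073877, plus strand, each as a whole gene in GRCm38 coordinates.

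The second comparison concerned thermogenic genes in single samples. Ppargc1a, the coactivator gene of mitochondrial biogenesis, stood at 2.32, 3.57 and 1.99 CPM of the total count in HFD 1 to 3. In THBru 1 to 3 it stood at 1.29, 17.7 and 8.53 CPM. Its TMM-scaled levels were 2.15, 3.49 and 1.84 CPM in HFD and 2.04, 14.9 and 7.64 CPM in THBru. Prdm16, a regulator of brown and beige adipocyte identity, stood at 9.49, 7.64 and 8.63 CPM of the total count in HFD and 6.12, 18.5 and 40.3 CPM in THBru. Its TMM-scaled levels were 8.79, 7.48 and 8.00 CPM in HFD and 9.68, 15.5 and 36.1 CPM in THBru. For THBru 1 the order against HFD therefore depended on the scaling. Ucp1, the uncoupling protein gene of thermogenic fat, had 31, 0 and 4 counts in HFD and 16, 15 and 0 counts in THBru. Lep, which encodes the satiety hormone leptin, was lower in each THBru library than in any HFD library, at 1705, 4223 and 1503 CPM against 130, 604 and 94.0 CPM.

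Among the 9 genes, Lep (difference of mean log2 values −3.49) and Cox8b (−0.90) reached the smallest p that the exact permutation test can give, 0.1. Cox8b, a muscle and brown fat cytochrome oxidase subunit gene, had 14, 10 and 13 counts in HFD and none in THBru, where 0 counts over the group allow up to 0.0144 CPM. The exact permutation p was 0.4 for Ppargc1a (difference 0.82) and Prdm16 (0.75), 0.5 for Cidea (−0.36) and Ppargc1b (−0.31), 0.2 for Elovl3 (−0.40), 0.9 for Dio2 (−0.03) and 1 for Ucp1 (0.01). Adjusted over the 9 genes, the smallest of these exact p-values was 0.45. In edgeR, Ppargc1a (log2 fold change 1.71, SE 0.75; adjusted p = 0.236), Prdm16 (1.34, SE 0.51; adjusted p = 0.206), Cidea (−0.38), Ppargc1b (−0.28), Lep (−3.16, SE 0.86; adjusted p = 0.172) and the adiponectin gene Adipoq (−1.53, SE 0.80; adjusted p = 0.288) did not pass. Ucp1, Dio2, Cox8b and Elovl3 fell under the minimum level for that test. Without THBru 2 Ppargc1a stood at 0.96 and Adipoq at −2.46, and without THBru 3 Prdm16 at 0.64. DESeq2 called Lep lower at an adjusted p of 6.7e-04. Each THBru library in these tests held transcripts of another organ, and the adipocyte list was at 0.183 and 0.0969 of its HFD mean in THBru 1 and THBru 3 and at 0.893 of it in THBru 2.

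**Figure D2:**
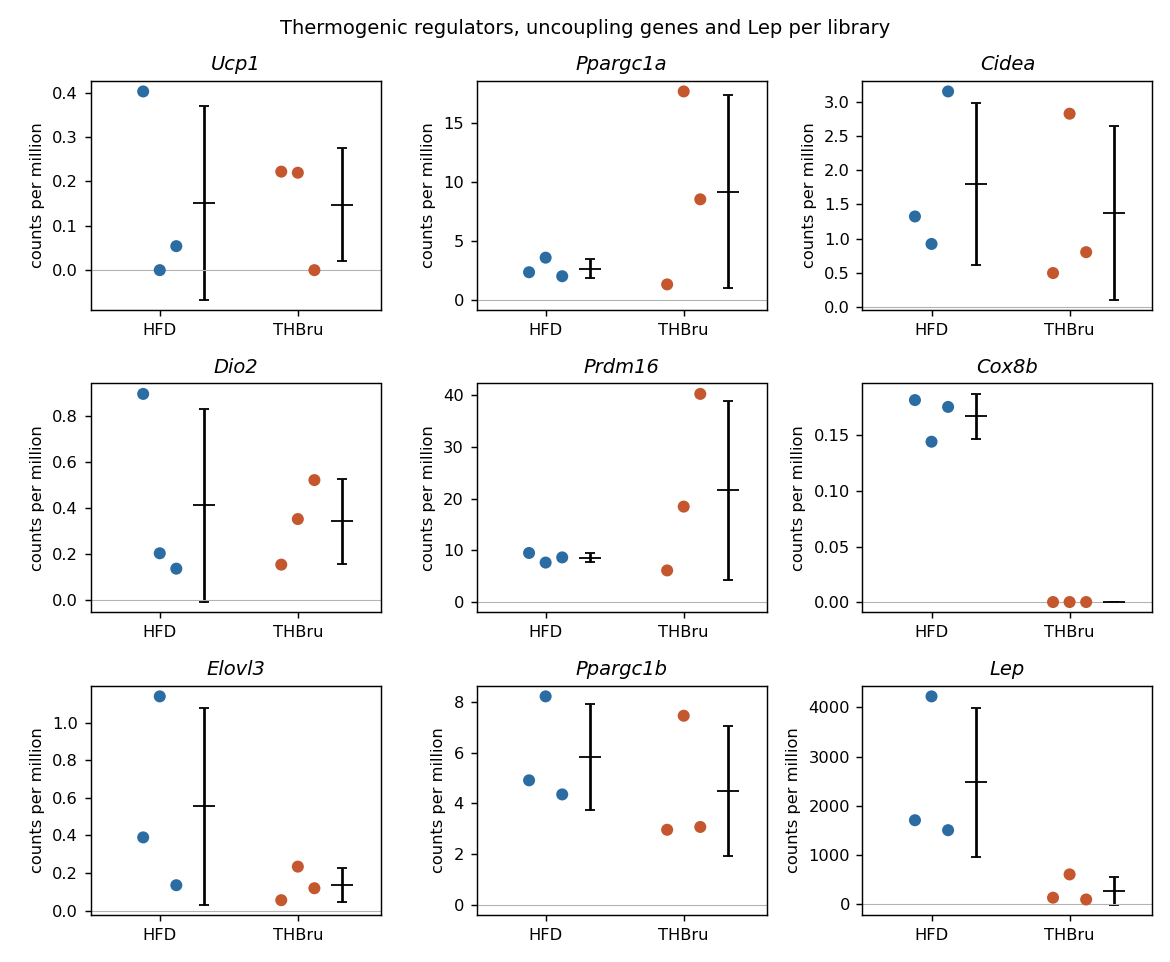
CPM of the total count for 9 genes, 1 point per library, with the mean and SD of 3 libraries as the black mark and bar. Ppargc1a is at 17.7 CPM in THBru 2 and 1.29 CPM in THBru 1, and the 3 THBru values of Lep lie below the 3 HFD values.

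The third comparison asked which gene groups moved together. Immune and matrix genes were the groups with the smallest p. The macrophage list fell, with a median log2 fold change of −2.02, and 25 of its 25 tested genes had negative fold changes, 15 of them passing when adjusted over the list alone and 0 over all genes (camera adjusted p = 1.0e-12, and 0.718 with an estimated correlation). Its members Cd68 (log2 fold change −2.72, SE 0.59) and Itgax (−3.13, SE 0.75), a lysosomal and an integrin gene of macrophages, did not pass alone. The lipid-associated macrophage list fell with a median of −1.89 (12 of 22 lower when adjusted over the list alone), with Lgals3 (−3.47, SE 0.71) and Ctss (−2.56, SE 0.58). The extracellular matrix list fell with a median of −1.86 (13 of 27 lower when adjusted over the list alone), with the collagen VI genes Col6a2 (−2.10, SE 0.44) and Col6a1 (−1.86, SE 0.44). The cell cycle list fell with a median of −1.57 (11 of 25 lower when adjusted over the list alone), with the cyclin genes Ccna2 (−2.06, SE 0.48) and Ccnb1 (−2.43, SE 0.59). Medians of the cell cycle list were 4.15, 3.46 and 2.12 log2 CPM in HFD 1 to 3 and 1.95, 1.77 and 1.83 in THBru 1 to 3. HFD 3 thus lay close to the THBru libraries, and the fall came mostly from HFD 1 and HFD 2. With an estimated correlation the adjusted p was 0.729 for the cell cycle list and 0.718 for the lipid-associated macrophage and matrix lists.

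Adipocyte lists also fell. Median log2 fold changes were −1.31 for mature adipocyte identity (20 of 22 genes negative, with Sncg at −1.98), −1.51 for lipid droplet coat (Plin2 −2.70, Bscl2 −0.97), −1.26 for lipolysis and adrenergic signalling (Hilpda −2.42, Adcy3 −1.52), −1.15 for triglyceride synthesis (Dgat2 −1.98, Gpd1 −1.39), −0.85 for white adipocyte enriched genes (Igfbp3 −1.91, Mest −3.67), −0.82 for fatty acid oxidation (Cpt1b −2.0, Hadha −0.74), −0.41 for insulin signalling (Irs2 −1.73, Socs3 −1.58) and −0.31 for the TCA cycle (Sucla2 −0.53, Pcx −1.31). In THBru 2 alone the medians of these lists were, in the same order, −0.25, −0.53, −0.44, −0.25, −0.39, −0.18, −0.18 and −0.01. Adipokines and secreted factors fell with a median of −1.28, while Bmp7 stood at 4.88. The inflammatory cytokine list (median −1.24; Il1rn −4.25, Cxcl1 −2.14), endothelial genes (−0.79, but 0.39 in THBru 2 alone; Robo4 −1.40, Emcn −0.79), progenitor and fibroblast genes (−0.82; Zfp423 −1.50, Col15a1 −1.69), neutrophil genes (−1.95; Csf3r −1.38, Retnlg −2.93) and MHC class II genes (−1.62; Ciita −2.20, H2-DMb2 2.89) fell as lists. With an estimated correlation the adjusted p of the lists in this paragraph was 0.718 to 0.826. None of these members passed alone over all genes. Without THBru 2 Robo4 stood at −2.77, Emcn at −1.64 and Pcx at −1.99, without HFD 1 Ciita at −1.46, without HFD 2 Retnlg at −1.08, and without THBru 3 H2-DMb2 at 1.26. Some calls ended when a library was left out: ribosomal proteins without THBru 1 (adjusted p = 0.0970), the TCA cycle without HFD 3 or THBru 3, insulin signalling without HFD 2 or THBru 3, neutrophil genes without HFD 2, THBru 1 or THBru 3, and MHC class II genes without any library but HFD 2.

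Higher lists were cytosolic ribosomal proteins (median 0.55, 42 of 45 genes positive, Rpl22 1.0, Rpl14 0.88), mammary and skin epithelium (median 8.10; Epcam, and Krt5 at 9.50) and epididymal epithelium (median 7.99, 14 of 15 genes higher when adjusted over the list alone; Defb42 7.92, Lcn10 8.39), with adjusted p-values of 0.795, 0.718 and 0.799 under an estimated correlation. The ribosomal rise was carried by THBru 1 and THBru 3, with list medians of 7.80, 6.83 and 7.30 log2 CPM in THBru 1 to 3 and 6.78 to 6.89 in HFD. The mammary and skin epithelium rise was carried by THBru 1 and THBru 3: list medians were 4.0, −1.24 and 5.01 log2 CPM in THBru 1 to 3 and −1.76 to −0.84 in HFD, and Krt5 had 1135, 23 and 4016 counts in THBru and at most 4 in HFD. The epididymal rise was largest in THBru 3: list medians were 1.73, 1.14 and 10.3 log2 CPM in THBru 1 to 3 and 0.77 to 0.81 in HFD, and Lcn10 stood at 1.14 without THBru 3. In THBru 2 alone the list did not pass (median 0.25; camera adjusted p = 0.652). The thermogenic and beige adipocyte list did not pass (median −0.00, mean 0.78, 8 of 16 genes positive; camera adjusted p = 0.646), with Cpt1b at −2.0 and Slc27a2, a fatty acid transporter gene, at 6.80, or 4.23 without THBru 2. Slc27a2 stood at 0.555, 182 and 20.6 CPM of the total count in THBru 1 to 3 and at 0.433 to 0.689 in HFD. THBru 2 and THBru 3 also held kidney and epididymal transcripts, so the rise of Slc27a2 cannot be assigned to fat cells. Respiratory complex I (median −0.08; Ndufb3 −0.96, Ndufb11 0.84; adjusted p = 0.465), complexes II to V (median −0.11; Cycs −0.66, Cox8a −0.48; adjusted p = 0.226) and de novo lipogenesis (median −0.11, mean 0.73; Scd2 3.14, G6pdx −1.49; adjusted p = 0.691) did not pass either.

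Of 47 lists, 21 passed with the preset correlation, 3 higher and 18 lower. With an estimated correlation 0 passed, and fry called 0. In THBru 2 against the 3 HFD libraries, a comparison chosen after seeing the data, the macrophage (median −1.39), lipid-associated macrophage (−1.53), matrix (−1.27) and cell cycle (−1.41) lists fell, as did the lipid droplet coat (−0.53), adipokine (−0.47), lipolysis (−0.44) and white adipocyte enriched (−0.39) lists, while mature adipocyte genes stood at −0.25 (camera adjusted p = 0.136). The erythrocyte (1.33), mammary and skin epithelium (1.11), circadian clock (0.67) and mitochondrial genome protein gene (0.56; camera adjusted p = 0.0142) lists rose. The unfolded protein response list fell there (−0.52), and in all 15 lists passed, 4 higher and 11 lower. That fit assumes that the lone THBru library varies like the HFD libraries. With adipocyte scaling added, the lipid droplet coat, lipolysis, circadian clock and mitochondrial genome protein gene lists no longer passed.

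**Figure D3:**
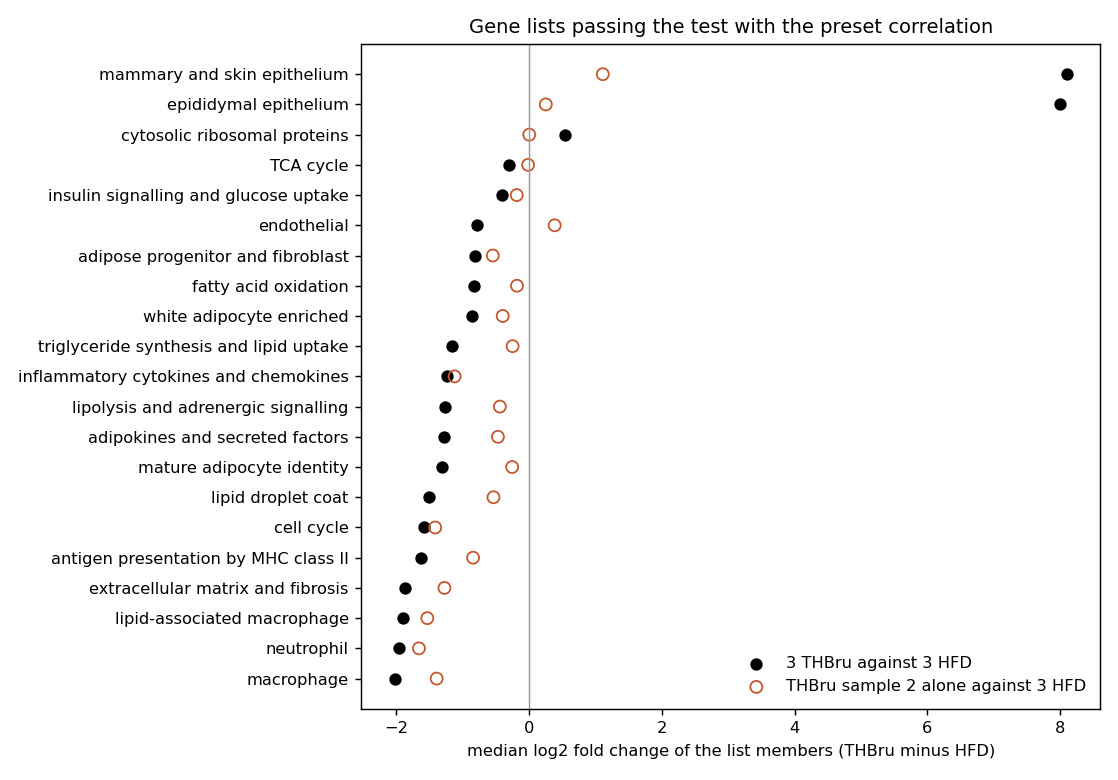
Median log2 fold change (THBru minus HFD) of the members of the 21 lists that passed with the preset correlation, for all 6 libraries (filled) and for THBru 2 alone against the HFD libraries (open). The macrophage list stands at −2.02 and −1.39, and the mature adipocyte list at −1.31 and −0.25.

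The fourth comparison used the annotated terms. Genes of motile cilia rose: cilium movement had a median log2 fold change of 3.97 (31 of 33 genes positive; camera adjusted p = 9.1e-07, and 0.986 with an estimated correlation), with Celsr2 at 3.97, Ttc25 at 3.94 and Dnah11 at 8.35, and motile cilium a median of 1.30 (74 of 90 positive; Stard10 5.09; adjusted p = 0.986 with an estimated correlation). Collagen-containing extracellular matrix fell (median −1.01, 128 of 171 genes negative; camera adjusted p = 3.1e-09, and 0.986 with an estimated correlation), with Serpinh1, a collagen chaperone gene, at −2.18, while Col23a1 stood at 1.82 and Lama1 at 6.06. The phagosome term fell (median −0.75, 111 of 138 negative; camera adjusted p = 3.2e-07, and 0.986 with an estimated correlation), and its member with the smallest p after Tubb2a, Itgb2l, stood at 5.43. None of these members passed alone. In all, 158 of 2283 terms passed, 39 higher and 119 lower, and 0 passed with an estimated correlation. The cilia terms moved beside the ciliated epithelium genes, which were higher in THBru 2 and THBru 3 and at 0.305-fold in THBru 1.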

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

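Of 16140 genes, 19 were called with all 6 libraries and 0 to 1552 with a library left out, 0 without any one HFD library and 1552 without THBru 2. DESeq2 called 2773 and, without the filter, 2798. Limma called 73, 118 with a pseudocount of 0.1, 56 with 1, 29 with median scaling, 75 not robust and 159 with quality weights. Settings chosen after seeing the data gave 357 (THBru 2 alone), 5379 (scaled to mature adipocyte genes), 1259 (both) and 53 (total counts). Filters, quantile normalization and DESeq2 size factors in edgeR gave 19 to 28. The causes were not tested.

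With the replicate number as a block, edgeR called 0 genes, and 21 of the gene lists between THBru and HFD and 143 of the annotated terms between THBru and HFD passed, and 4 thermogenic genes had 3 same-sign pair differences. Same-numbered deviations correlated at 0.010, −0.006 and −0.047, and differently numbered ones at −0.035 to 0.039. Each THBru library held transcripts of another organ, so this check could neither show nor exclude a pairing. The numbers were not read as pairs.

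Lists passing were 21, 19 to 23 with a library left out, 10 for THBru 2 alone scaled to adipocyte genes, 0 with an estimated correlation and 0 with fry. Terms passing were 158, 119 to 194 with a library left out and 0 with an estimated correlation. Thermogenic genes with no overlap were 2, 2 to 5 with a library left out and 5 with quantile normalization.

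Leaving out a library gave a Ucp1 difference of mean log2(FPKM + 0.5) of −0.093 to 0.18, Cidea −0.86 to 0.025 and Dio2 −0.083 to 0.074, Ppargc1b log2 fold changes of −0.58 to 0.10 and Cidea −1.16 to 0.28. The thermogenic and beige adipocyte list adjusted p ranged from 0.273 to 0.754 (direction turned without THBru 1), the complex I nuclear subunits list adjusted p from 0.103 to 0.934 (turned without HFD 3) and the de novo lipogenesis list adjusted p from 0.316 to 0.847 (turned without THBru 1). Quantile normalization turned the direction of Ucp1 (−0.15), de novo lipogenesis (adjusted p 0.808) and complexes II to V (complex II to V nuclear subunits list adjusted p 0.815), and adipocyte scaling turned complex I and complexes II to V (0.917 each).

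In THBru 2 alone, and then with adipocyte scaling, turned values were Ppargc1b 0.19 and 0.21, Cidea 0.51 and 0.58, Emcn 0.15 and 0.17, and adjusted p-values of 0.697 and 0.731 for ribosomal proteins, 0.186 and 0.285 for endothelial genes, 0.139 and 0.132 for the thermogenic list, and 0.0742 and 0.0876 for de novo lipogenesis. The epididymal list turned with both (0.970). Gene values under adipocyte scaling are relative to its shift of all genes, 2.18 log2 (0.24 for THBru 2 alone), and under total counts to −0.13. Before subtraction, 23 of the 51 lower named genes read higher under adipocyte scaling. Among other values, counted once per result and setting, 1986 kept their direction and, where a threshold applied, their side of it. A further 133 fell short of the threshold and 155 newly passed. Ucp1 counts of 0 to 31 limit what could be seen.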

Other observations

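All tests in this part were chosen only after the results were seen. Setting each library's levels against its own mature adipocyte list moves the median difference of the 16140 tested genes to 1.79 log2, the value of a gene that follows the rest. On that scale, with HFD libraries averaging near 0, Mest, an imprinted gene linked to fat cell enlargement, stood at −3.05, −2.18 and −2.57 log2 in THBru 1 to 3 and between −0.16 and 0.35 in HFD (exact permutation p = 0.1, the smallest possible). Lgals3 differed by −1.81 and Adipoq, itself in the adipocyte list, by −0.25 (−0.31 against the other 21 genes) at the same exact permutation p, which is 0.133 adjusted over the 8 genes compared, while Cd68 (−0.94, exact permutation p = 0.4) and Col6a2 (−0.45, exact permutation p = 0.6) overlapped. Cidea differed by 1.52, or by −0.27 after that median was subtracted.

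Genes specific to THBru 1 or THBru 3 appeared at a low level in every other library. With 95% of a gene's counts and at least 20000 counts in the source, the median level was 0.129 to 0.204% of the THBru 1 count over 14 genes and 0.129 to 0.198% of the THBru 3 count over 48 genes. A stricter share, also tried, gave 0.128 to 0.201% over 12 genes and 0.129 to 0.190% over 41. If these counts came from the source libraries, the 740-fold and 808-fold values, whose HFD means are 612 and 38.8 CPM, are lower bounds.

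Beside the 19 genes higher in THBru, each THBru library holds the transcripts of a different organ. A candidate explanation is that tissue other than fat was in the THBru libraries: the tissue list of each was raised at least 616-fold over the HFD mean, all members included, though the seminal vesicle and kidney lists were written after those genes had been seen. A common response to THBru was not seen for most of the genes most raised in each library: the 3 lists of 100 genes shared 2, Cdh1 and Epcam, though pairs shared 7, 6 and 9 where chance gives 0.620. Whether fewer genes, the 19 among them, respond to THBru stays open, as treatment and tissue fall in the same libraries. The real grouping gave 19 genes and the highest other split 0, so 1 of 10 splits, the real one, was as large, too few splits for a share under 0.05.

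Adipocyte, macrophage and matrix lists were lower in THBru. Dilution of adipose RNA may account for part. Relative to the adipocyte list the macrophage difference was −0.40 (exact permutation p = 0.7) and the matrix difference −0.12 (exact permutation p = 0.8). HFD 1 lay highest of the HFD libraries for both, at 1.20 and 0.85. HFD 2 and HFD 3 stood at −0.47 and −0.67 for macrophage genes and at 0.04 and −0.71 for matrix genes. For macrophage genes THBru 1 (−0.19) and THBru 3 (0.02) lay within the HFD range. THBru 2, whose adipocyte score was −0.10, lay at −0.98, below the lowest HFD library at −0.67. The cell cycle difference on this scale was 0.55 (exact permutation p = 0.7). The median of all genes stood at 1.74, 0.25 and 3.36 in THBru 1 to 3 on this scale. Macrophage or matrix transcripts from another organ would also raise these values. The scale therefore cannot show how much of the macrophage and matrix falls is dilution. For Lep, itself in the adipocyte list, the difference that remained was −1.61, or −1.66 against the other 21 genes (exact permutation p = 0.1 for each). Relative to the full list Lep stood at −1.70, −1.78 and −1.29 in THBru 1 to 3, below the lowest HFD library at −0.85. In THBru 2, which kept its adipocyte score, Lep was at 604 CPM, below every HFD library. A dilution that lowers adipocyte genes alike would leave no difference on this scale. The gap between the groups was smaller than the HFD SD of 0.87 or 0.90, so a change of Lep beyond dilution was not settled with 3 libraries a group. For lists, 5 of 10 splits, the real one included, gave at least the 21 of the real grouping (highest other 27), and for terms 4, counted the same way, gave at least 158 (highest other 219). With 10 splits no share under 0.05 is possible.

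Ppargc1a relative to the adipocyte list differed by 3.01 log2 (1.6, 2.67 and 4.83 in THBru 1 to 3), 1.23 above the median of all genes on that scale. In THBru 1 it stood at 2.04 TMM-scaled CPM, within the HFD range of 1.84 to 3.49. On the total count, Ppargc1a there stood at 1.29 CPM, below every HFD library. Relative to the median gene of each library it stood at −0.13, 2.42 and 1.46 in THBru 1 to 3 and −0.31 to 0.46 in HFD. Higher Ppargc1a in adipocytes could give what is left, and so could Ppargc1a from other tissue, since kidney and other epithelia use the gene. In THBru 2, which kept its adipocyte score, Ppargc1a was 6.74-fold above the HFD mean and the kidney list 616-fold. The explanations cannot be told apart, because no THBru library lacks transcripts of another organ.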
